A study of Homo sapiens with 12 samples.

How the data were processed

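The data are 12 Illumina BeadChip arrays of total RNA from the human chondrocyte cell line C28/I2, all on 1 BeadChip. Per the labels, RNA was extracted with Trizol, cleaned up, treated with DNase I and labelled by the standard Illumina protocol. The transfection labels give 4 groups of 3 arrays, and the sample titles carry the opposite prefix for the silencing and overexpression groups; the labels were used for grouping. Along the BeadChip the arrays labelled silencing lie at positions 1 to 3 and the control arrays at 10 to 12, while the scrambled siRNA arrays and the arrays labelled overexpression alternate between them.

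The deposited value table holds a probe intensity on a linear scale for 48803 probes on each array. All 12 arrays share 1 distribution of deposited intensities, as quantile normalization leaves it, but the method of normalization and background correction is not given in the sources used here and cannot be undone. A second deposited table of the authors lists 1842 probes with group means and standard deviations on the log2 scale, a p-value and FDR of an overall test, and a p-value and signed fold change for each pair of groups. The authors' group means were within 8.03e-05 of the mean of log2 of the intensity plus 16, and their overall p-values were within 0.00186 log10 units of those of a one-way analysis of variance over the 4 groups on that scale. Their FDR corresponded to about 25352 tested probes. Of 1935 probes with an overall p as small as the largest in the table, 93 are missing from it, all with a mean log2 intensity of at most 6.89.

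Probe names come from that table, since no other annotation of the array was at hand. RefSeq accessions gave current symbols to 1544 probes, of which 216 differ from the symbol in the file; for 231 probes the file's symbol was kept, and 67 had none. After 2 probes were left out, 1773 probes of 1640 genes were named, and 47030 probes in the value table had no name. Statements on named genes therefore cover genes that the authors had selected on these samples. No DA125942 probe is named in either table.

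Log2 intensities of all 12 arrays were fitted with group means in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 8 residual and 7.56 prior degrees of freedom and no block or covariate. The 2 planned main comparisons were labelled silencing against scrambled siRNA and labelled overexpression against control. The other pairs of groups, and the difference between the 2 main effects, were tested in the same fit. Two-sided p-values were adjusted by Benjamini-Hochberg over all 48803 probes, and an adjusted p under 0.05 was called. For PTHLH and SOX9 an exact two-sided permutation test was run beside the fit, whose smallest p for 3 arrays against 3 is 0.1. Across probes, pairs of arrays had a Pearson correlation of log2 intensity of 0.983 to 0.993 within groups and 0.979 to 0.992 between groups. The number of arrays limits the precision. Other tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

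The comparisons, the tests, the gene lists, the first set of alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each main comparison, the 12 named genes with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05 and no overlap between the groups, and 5 per direction in the other comparisons. For the difference of the 2 effects the overlap was judged between the arrays labelled silencing and scrambled siRNA. PTHLH, SOX9 and up to 4 members of each described list, those with the smallest p, were always named. Where a gene had several probes, the one with the highest mean over the 12 arrays was used; of 118 such genes 104 had at least 2 called probes for silencing against scrambled siRNA, and 1 of them, PHF19, had calls in opposite directions. List members outside this rule, such as TIGAR, TNFRSF10B, ZNRF3, AAAS and HOXC10, were named after their values were seen, because they make up a small count.

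The 27 gene lists held 620 symbols. The 12 lists with at least 3 named members were tested against the other named genes with camera at a preset correlation of 0.01, adjusted over lists, and beside it with an estimated correlation and with fry. Members were also counted with the p adjusted over the list alone. The relation between the 2 effects was described by correlation across probes and set against 100 simulations without effects, which drew each probe independently.

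Alternatives were an added offset of 16, median centring, a further quantile normalization, a trend and robust moderation, array weights, position along the BeadChip as a covariate, the replicate number as a block, only the arrays compared, only the brighter probes, the mean over a gene's probes, a minimum of 1.5-fold, and leaving out each replicate in turn. Added after the data were seen were a covariate for a shared axis of the within-group deviations, unmoderated contrasts on the authors' scale, and tests of gene families by symbol. The procedure was tested on simulated data with changes of known size added to arrays drawn with each probe's fitted spread. The noise was drawn independently for each probe, and only probes brighter than the median were changed. The recovery of dim probes and false calls from deviations shared between arrays were therefore not tested. Of the changed probes 53.7% were called at 1.5-fold, 95.5% at 2-fold and 100% at 4-fold in the first main comparison, and 50.7%, 94% and 100% in the second. False calls were 10 of 176 and 11 of 174, and of the lists, the raised one was called with 0 others.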

Results

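The series holds 12 BeadChip arrays of C28/I2 human chondrocytes after transient transfection. The study altered DA125942, the transcript of the long non-coding RNA of the CISTR-ACT locus, in both directions. The transfection labels define 4 groups of 3 arrays: silencing, overexpression, scrambled siRNA and control. The sample titles contradict these labels. Arrays labelled silencing carry titles without the prefix si, and arrays labelled overexpression carry titles with it. The sample descriptions and the group names in the authors' result table follow the transfection labels. The groups below follow the transfection labels and are called arrays labelled silencing and arrays labelled overexpression, and no measured value was used to decide which naming is right. Each labelled group was compared with both control groups. No probe could be assigned to DA125942, so the level of the targeted transcript is not known here. Nothing in the labels says that the 3 replicates of a group were separate cultures, so the p-values measure the spread between these samples.

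PTHLH, which encodes parathyroid hormone-related protein, a regulator of chondrocyte maturation, was lower in the arrays labelled silencing than in the scrambled siRNA arrays. Its mean log2 intensity was 8.24 ± 0.07 (SD, 3 arrays) against 9.28 ± 0.21, a log2 change of -1.04 with a standard error of 0.17 (limma, adjusted p = 0.00115). In the arrays labelled overexpression the mean was 8.53 ± 0.47 against 9.17 ± 0.12 in the control arrays, a log2 change of -0.64 that did not pass the test (adjusted p = 0.139). All 3 values of each labelled group lay below all 3 of its control group, which the exact two-sided permutation test rates at p = 0.1, the smallest value 3 arrays against 3 can give. SOX9, the master transcription factor of cartilage, had a mean of 10.51 ± 0.08 in the arrays labelled silencing and 11.56 ± 0.05 in the scrambled siRNA arrays. This log2 change of -1.05, standard error 0.11, passed the test (adjusted p = 3.35e-05), with an exact permutation p of 0.1. In the arrays labelled overexpression SOX9 was at 10.98 ± 0.13 against 11.13 ± 0.25 in control, a log2 change of -0.15 (adjusted p = 0.802, exact permutation p = 0.5). The difference between the 2 effects passed the test for SOX9 (-0.90, adjusted p = 0.00595) and not for PTHLH (-0.40, adjusted p = 0.56). It includes the gap between the 2 control groups, whose SOX9 means were 11.56 and 11.13.

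Against the control arrays in place of scrambled siRNA, the arrays labelled silencing had lower PTHLH (-0.93, adjusted p = 0.00354) and lower SOX9 (-0.61, adjusted p = 0.0036). Against scrambled siRNA in place of control, the arrays labelled overexpression had lower SOX9 (-0.58, adjusted p = 0.027), and PTHLH had a log2 change of -0.75 (adjusted p = 0.0658). The 2 control groups differed by 0.11 for PTHLH and 0.44 for SOX9, with adjusted p-values of 0.998 and 0.721. Between the labelled groups SOX9 was lower in the arrays labelled silencing (-0.46, adjusted p = 0.0239), and PTHLH had a log2 change of -0.29 (adjusted p = 0.484). Over these 4 comparisons the exact permutation p was 0.5 for PTHLH between the controls and between the labelled groups, and 0.1 otherwise. The PTHLH probe covers bases 28007752 to 28007801 of chromosome 12 and the SOX9 probe bases 67633576 to 67633625 of chromosome 17, in a genome build that the sources used here do not give.

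PTHLH and SOX9 calls depended on settings in several places. With position along the BeadChip as a covariate, the PTHLH change against scrambled siRNA in the arrays labelled silencing was -0.60 (adjusted p = 0.122), that against control 0.06 (adjusted p = 0.982), and that of SOX9 against control -0.38 (adjusted p = 0.738). Without replicate 3 of the arrays labelled overexpression, PTHLH passed the test against control (-0.90, adjusted p = 0.00291) and against scrambled siRNA (-1.02, adjusted p = 0.00119). The latter also passed with a trend and robust moderation (adjusted p = 0.0466), with array weights (0.0378), with the replicate number as a block (0.0321) and with the position covariate (0.00814). The SOX9 call of the arrays labelled overexpression against scrambled siRNA ended without replicate 1, 2 or 3 of scrambled siRNA (adjusted p = 0.0921, 0.128 and 0.0698) and without overexpression replicate 1 or 3 (0.104 and 0.0841). The SOX9 call between the labelled groups ended without silencing replicate 1 or 3 (adjusted p = 0.0838 and 0.101), without overexpression replicate 2 (0.119) and with the position covariate (0.535). By unmoderated contrasts, chosen after the data were seen, the adjusted p was 0.0786 for PTHLH in the arrays labelled silencing against control and 0.0703 for the SOX9 difference between the 2 effects. For SOX9 by these contrasts, the adjusted p was 0.21 for labelled overexpression against scrambled siRNA and 0.111 between the labelled groups, so all 4 calls ended.

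**Figure D1:**
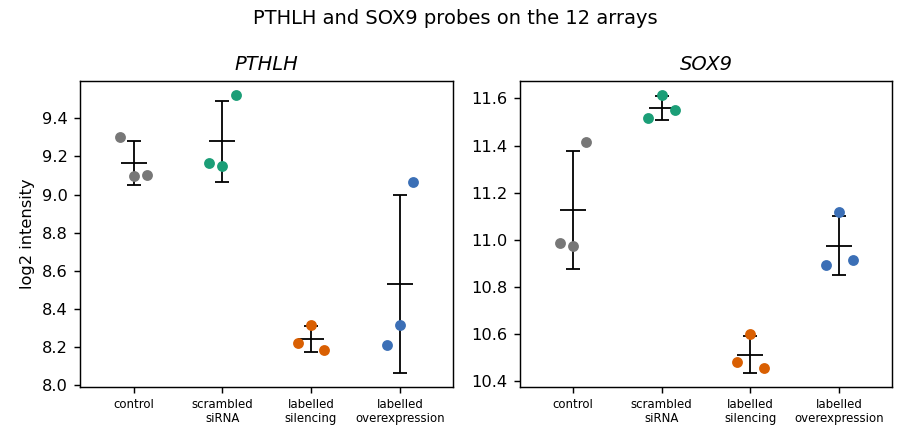
Log2 intensity of the PTHLH and SOX9 probes on each of the 12 arrays (points), with the mean and SD of the 3 arrays of a group (bars). The arrays labelled silencing had means of 8.24 for PTHLH and 10.51 for SOX9, below the scrambled siRNA means of 9.28 and 11.56, and the axes do not start at 0.

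In the arrays labelled silencing, ATF3, a stress-induced transcription factor, was 10.3-fold higher than in scrambled siRNA (log2 change 3.36, standard error 0.13, 3 arrays per group, adjusted p = 1.05e-09). TAGLN and ACTG2, which encode an actin-binding protein and an actin of smooth muscle, were higher by 3.21 (standard error 0.335) and 2.79 (standard error 0.11) on the log2 scale. GADD45A rose by 2.34, DDIT3 by 2.10 and PPP1R15A by 2.02; these are growth-arrest and stress genes, and PPP1R15A directs the dephosphorylation of the initiation factor eIF2alpha. KLF2, a transcription factor, rose by 2.06, and FGFR3, a growth factor receptor of growth plate cartilage, by 2.001. TXNIP, an inhibitor of thioredoxin, rose by 1.97, the histone gene H4C14 by 1.86 and TOMM20, a receptor for mitochondrial protein import, by 1.85. The probe named NBPF9 rose by 1.92; the deposited file calls it NBPF20, and the copies of this family are so alike that its assignment is uncertain.

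Among the named genes the largest fall was that of PLAT, tissue-type plasminogen activator, at -2.66 (standard error 0.24, adjusted p = 5.41e-06). HOXB8, a homeobox transcription factor, fell to a similar degree (-2.65, standard error 0.13, adjusted p = 2.5e-08), as did TNFRSF11B, the decoy receptor osteoprotegerin (-2.62). SLC14A1, a urea transporter, changed by -2.44, and ITGA2, a subunit of a collagen-binding integrin, by -2.33. Lower values were also found for CST1 (-2.19), a cystatin, LRRC17 (-1.98), AP1S1 (-1.97), a clathrin adaptor subunit, and ST3GAL5 (-1.78), a ganglioside synthase. CCN3, a matricellular protein, and FAM43A both changed by -1.75, and SLCO4A1, an organic anion transporter, by -1.73. The rule for named genes required that the values of the 2 groups do not overlap, so for these 24 genes this adds no support. Chance gives no overlap to 10% of probes with 3 arrays against 3. The AP1S1 probe spans an intron in the coordinates given with it.

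In all, 3430 of 48803 probes passed the test in this comparison, 1840 higher and 1590 lower, and 403 of them changed at least 2-fold. Gene names were available only for probes of the deposited result table, which the authors selected on these samples. Among the 1640 named genes 780 were higher and 581 lower, and 1948 of the called probes have no name here. Without replicate 2 of the arrays labelled silencing 2262 probes passed.

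**Figure D2:**
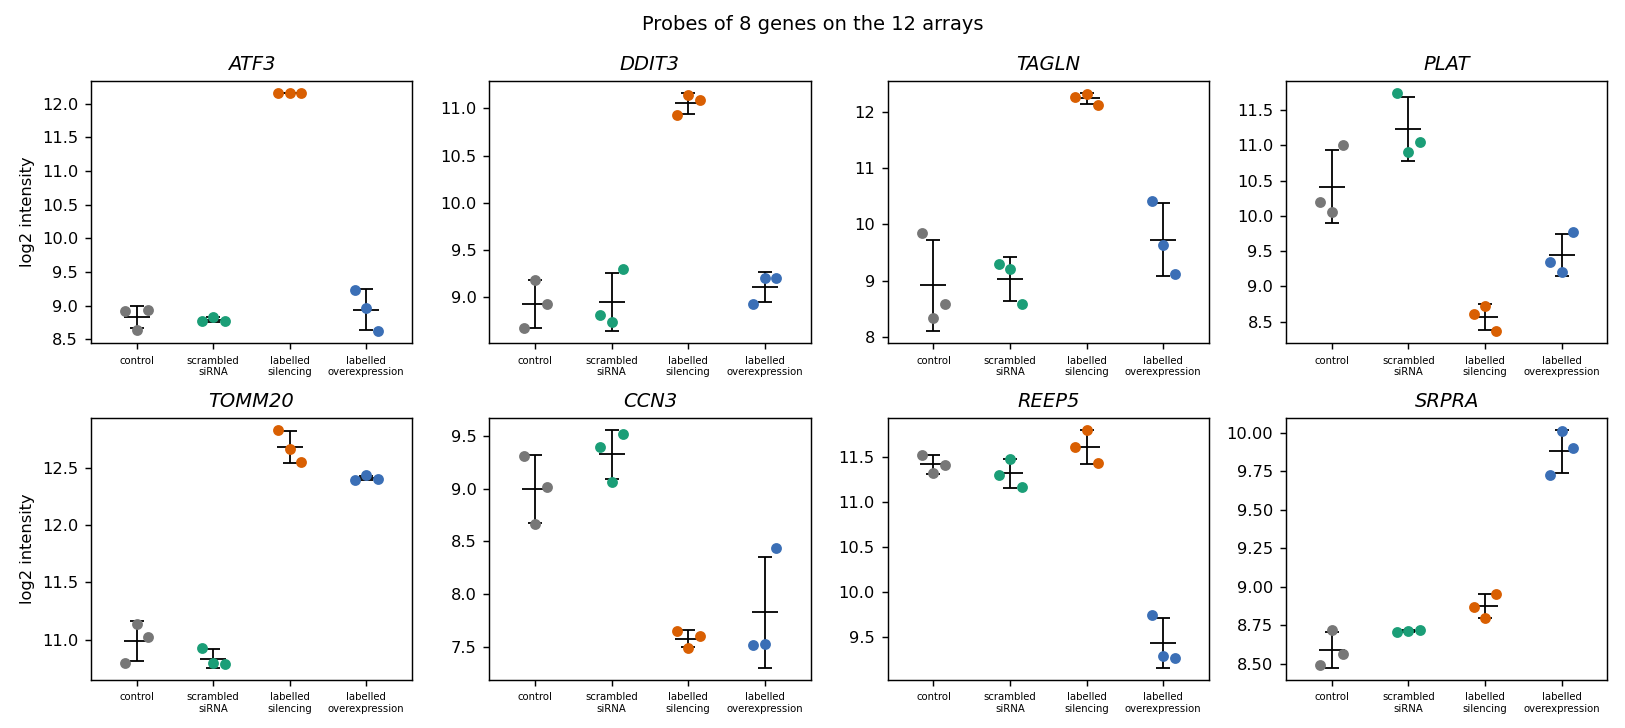
Log2 intensity of the probes of 8 named genes on each of the 12 arrays (points), with the mean and SD of the 3 arrays of a group (bars); the axes differ between panels and do not start at 0. ATF3 differed by 3.36 between the arrays labelled silencing and scrambled siRNA, TOMM20 was higher in both labelled groups, and REEP5 changed by -1.99 in the arrays labelled overexpression against control.

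Stress genes rose together in the arrays labelled silencing. All 7 named members of the unfolded protein and integrated stress response list were higher than in scrambled siRNA, 7 also adjusted over the list alone, among them ATF3 (3.36), DDIT3 (2.10), DDIT4 (1.78) and TRIB3 (1.63). The list moved up relative to the other named genes by camera (adjusted p = 0.0109), with an adjusted p of 0.172 with an estimated correlation. All 5 named immediate early genes rose, 5 also adjusted over the list alone, including KLF2 (2.06), EGR1 (1.55) and ZFP36 (1.13). The list of short-lived transcripts was fixed as a sign of how cells or RNA were handled, and all 5 of its named members rose with the stress genes, 5 also adjusted over the list alone, including KLF10 (1.45) and SERTAD1 (1.24). Both lists had a camera adjusted p of 0.0223 and an adjusted p of 0.172 with an estimated correlation, and ATF3 is a member of all 3 lists. PPP1R15A is in the stress response and short-lived lists, and ZFP36 in the immediate early and short-lived lists. The 3 lists are therefore not separate support for each other, here or in the comparisons below. Because the named genes were selected on these samples, none of these counts, over all probes or over a list alone, is independent evidence of a list's direction.

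Of the 6 named p53 targets 4 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.506). GADD45A (2.34), PMAIP1 (0.72) and GDF15 (0.59) rose, TIGAR fell (-0.56), and TNFRSF10B had a log2 change of 0.16 that did not pass. The interferon response list had 3 members up and 2 down of 7 (4 and 3 adjusted over the list alone), with MX1 at 0.91, IFI27 at 0.82, HERC6 at -0.73 and SAMD9 at -1.05. Its median was 0.28 and its mean 0.05, while camera, which compares it with the other named genes, pointed down (adjusted p = 0.908). LCN2 (1.41) and CXCL2 (0.92) rose among 3 inflammatory genes (2 adjusted over the list alone, camera adjusted p = 0.605). Of 3 hypoxia and glycolysis genes ADM (1.45) and STC2 (0.49) rose and ERO1A (-0.86) fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.89). All 3 named subunits of oxidative phosphorylation fell, with log2 changes of -0.52 for NDUFA1, -0.46 for UQCRC2 and -0.44 for NDUFA9 (3 adjusted over the list alone, camera adjusted p = 0.224).

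Among the 3 named members of PTHrP and hedgehog signalling, PTH1R, the receptor of the PTHLH product, was higher (0.69), and PTHLH (-1.04) and PTCH1 (-0.37) were lower. The numbers adjusted over the list alone were the same, 1 higher and 2 lower, and the camera adjusted p was 0.728. Of the chondrogenic transcription factors CREB5 (1.001) and RUNX3 (0.67) were higher and SOX9 (-1.05) lower, 2 and 1 adjusted over the list alone (camera adjusted p = 0.89). Of 3 Wnt targets NKD2 (0.97) rose, TNFRSF19 (-0.50) fell and ZNRF3 (0.34) did not pass, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.907). Around 12q13.13 COPZ1 rose (0.49) and ITGA5 fell (-0.91), while HOXC10 (-0.27) and AAAS (-0.23) did not pass (1 and 3 adjusted over the list alone, camera adjusted p = 0.605). Lists with fewer than 3 named members were not tested as sets. Their members were TIMP3 (-1.02), which fell with PLAT, ACTA2 (1.16), which rose with TAGLN, and CSPG4 (0.42), CDT1 (0.51), SLBP (0.46), UBE2C (0.49) and HSPA6 (0.56), which rose. NOG (-0.97) and PPFIBP1 (-0.59), a neighbour of PTHLH, fell. The TGF-beta and BMP list, which holds NOG, also holds KLF10, and the histone list holds H4C14 (1.86). Both of these rose, as given above. Of markers of other cell types, the leukocyte gene LCP1 rose (1.42), and the adipocyte factors CEBPA and PPARG changed by 1.57 and -0.59. Adjusted over the list alone, each of these lists gave the same calls. No epithelial, endothelial, hypertrophic chondrocyte or sterol synthesis gene of the lists was among the named genes.

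**Figure D3:**
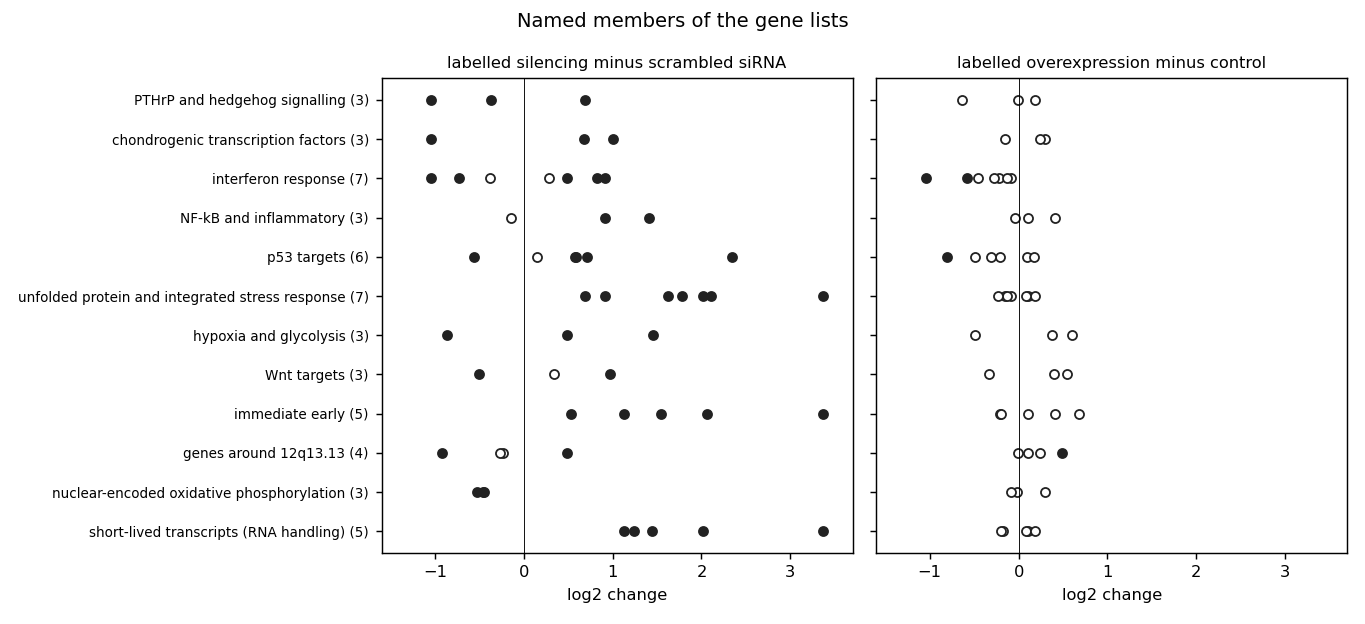
Log2 change of each named member (point) of the 12 gene lists with at least 3 named members, for the arrays labelled silencing against scrambled siRNA (left) and the arrays labelled overexpression against control (right). Filled points passed an adjusted p under 0.05: all 7 stress response genes are filled on the left, and 2 of 7 interferon response genes on the right.

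In the arrays labelled overexpression, REEP5, which shapes the endoplasmic reticulum, was lower than in control, with a log2 change of -1.99 and a standard error of 0.13 (3 arrays per group, adjusted p = 6.66e-06). TOMM20 was the named gene with the largest rise (1.43, standard error 0.10, adjusted p = 7.43e-06). CLDN1, a tight junction protein, rose by 1.33, and SRPRA, a subunit of the signal recognition particle receptor, by 1.29 (adjusted p = 7.48e-06). CALU, a calcium-binding protein of the secretory pathway, rose by 1.16, and MCFD2, part of a cargo receptor between endoplasmic reticulum and Golgi, by 0.96. Further rises were those of KLC1 (1.09), a kinesin light chain, CIRBP (1.09), a cold-induced RNA-binding protein, and CCND2 (1.06, adjusted p = 0.0316), a cyclin. BANF1 (0.999), H1-10 (0.99) and BOD1 (0.98), which act in chromatin and chromosome alignment, and MSRB3 (0.97), a methionine sulfoxide reductase, completed the 12 largest rises of named genes. Falls after REEP5 were those of ERRFI1 (-1.27), an inhibitor of the EGF receptor, CCN3 (-1.17), ZMPSTE24 (-1.08), the prelamin A protease, and IFIT3 (-1.04), an interferon-induced gene. FAM3C changed by -1.01, SPART by -0.995, LARP6, which binds collagen mRNA, by -0.99, and CCNA1 and RBM7 by -0.96 each. The mitochondrial genes CMC1 (-0.94) and ABCB10 (-0.89) were also lower, and the probes of CCNA1 and CMC1 span introns.

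Here 286 probes passed the test, 148 higher and 138 lower, 20 of them at least 2-fold, and 4473 had an unadjusted p under 0.05 against 2440 expected by chance. Of the 1640 named genes 104 were higher and 96 lower, and 66 called probes have no name here. The count moved with single arrays: 83 probes passed without overexpression replicate 2, 185 without overexpression replicate 1, 118 without control replicate 3 and 469 without control replicate 1, and 39 passed when only these 6 arrays were fitted. With the position covariate 157 passed, 61 of them among the 286, and by unmoderated contrasts, chosen after the data were seen, 42 passed. These contrasts ended the calls of CIRBP (adjusted p = 0.0547), FAM3C (0.0547), RBM7 (0.0556), IFIT3 (0.119), MSRB3 (0.137), H1-10 (0.198), ERRFI1 (0.198), LARP6 (0.198), CCN3 (0.252), CCNA1 (0.267) and CCND2 (0.316). Calls of CCND2, H1-10, ERRFI1, CCN3, LARP6 and CCNA1 ended when single arrays were left out: CCND2 without overexpression replicate 1 or 2 (adjusted p = 0.0782 and 0.169), H1-10 without overexpression replicate 1 or 2 or control replicate 3 (0.0515, 0.0723 and 0.0587), ERRFI1 without overexpression replicate 2 or control replicate 3 (0.0655 and 0.0554), CCN3 without overexpression replicate 1 or 2 or control replicate 3 (0.0788, 0.105 and 0.0716), LARP6 without overexpression replicate 2 or control replicate 3 (0.0538 and 0.0655), and CCNA1 without overexpression replicate 2 or 3 (0.118 and 0.0597). With the position covariate the calls of H1-10 (0.46), MSRB3 (0.54), ERRFI1 (-0.69), CCN3 (-0.82), CCND2 (1.05) and ABCB10 (-0.72) ended, with adjusted p-values of 0.277, 0.149, 0.237, 0.251, 0.165 and 0.0519. With only these 6 arrays fitted, the calls of CCND2, H1-10, ERRFI1, CCN3, LARP6, CCNA1 and IFIT3 ended, with adjusted p-values of 0.0759 (IFIT3) to 0.218 (CCND2).

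Of the gene lists, 1 moved in this comparison. In the interferon response list IFIT3 (-1.04) and IRF1 (-0.58) fell, 2 of 7 named members, and 4 were lower adjusted over the list alone, with SAMD9 at -0.46 and IRF7 at -0.28. The camera adjusted p was 0.0447, with an adjusted p of 0.616 with an estimated correlation, and the call ended without overexpression replicate 3 or without control replicate 1. TNFRSF10B (-0.80), a death receptor, fell among 6 p53 targets, with 3 lower adjusted over the list alone (camera adjusted p = 0.257). COPZ1 (0.48) rose among 4 genes around 12q13.13, with 2 higher adjusted over the list alone (camera adjusted p = 0.484). In the unfolded protein and integrated stress response list 0 of 7 genes passed by limma, and 0 adjusted over the list alone, with XBP1 at -0.23, DDIT3 at 0.19 and ATF3 at 0.11 (camera adjusted p = 0.832). The other tested lists had camera adjusted p-values of 0.832 to 0.915 and no called member over all probes. Adjusted over the list alone, 2 hypoxia genes were higher (ADM 0.60, STC2 0.37) and 1 lower (ERO1A -0.49), 2 Wnt targets were higher (NKD2 0.55, ZNRF3 0.40) and 1 lower (TNFRSF19 -0.33), and 2 immediate early genes were higher (KLF2 0.68, EGR1 0.41). By the same count BIRC3 (0.41) and NDUFA9 (0.30) were higher and PTHLH (-0.64) was lower. The median, the mean and the direction of camera differed in sign for oxidative phosphorylation and short-lived transcripts.

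Against the control arrays, the arrays labelled silencing had 2756 called probes, 1509 higher and 1247 lower. TAGLN (3.33), ATF3 (3.32), ACTG2 (2.81), DDIT3 (2.12) and GADD45A (2.07) rose most among the named genes, and TNFRSF11B (-2.50), ITGA2 (-2.25), HOXB8 (-2.18), SLC14A1 (-1.93) and LRRC17 (-1.92) fell most. The stress response list (camera adjusted p = 0.0079), the immediate early genes (0.0313) and the short-lived transcripts (0.0243) were higher, each with an adjusted p of 0.169 with an estimated correlation. With position along the BeadChip as a covariate 474 probes passed; the change was 0.88 for TAGLN, -1.48 for TNFRSF11B, -0.12 for SLC14A1 and 0.01 for ITGA2, none of which passed. Without silencing replicate 2 there were 1680 called probes, and without silencing replicate 3 there were 1752.

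Against scrambled siRNA, the arrays labelled overexpression had 298 called probes, 152 higher and 146 lower. TOMM20 (1.58), CIRBP (1.43), SLC66A3 (1.19), LZTFL1 (1.17) and SRPRA (1.16) rose most, and REEP5 (-1.89), PLAT (-1.79), CCN3 (-1.50), DMBT1 (-1.39) and CCNA1 (-1.29) fell most. The interferon response list was lower with 2 called members (camera adjusted p = 0.00858), with an adjusted p of 0.729 with an estimated correlation. The count was 118 without scrambled siRNA replicate 1, 121 without scrambled siRNA replicate 2 and 133 without overexpression replicate 2. By unmoderated contrasts, chosen after the data were seen, 44 probes passed. The calls of PLAT, CCN3, DMBT1, CCNA1 and SLC66A3 ended by these contrasts, with adjusted p-values of 0.148, 0.154, 0.07, 0.15 and 0.172.

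Between scrambled siRNA and control no probe passed by limma, with a smallest adjusted p of 0.21. An unadjusted p under 0.05 was found for 2615 probes, 1256 higher and 1359 lower, where 2440 are expected by chance. Unmoderated contrasts of a one-way analysis of variance called 1 probe. The count was 3 without control replicate 1, 1 without control replicate 2 and 1 without control replicate 3.

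The arrays labelled silencing were also compared with the arrays labelled overexpression, and 2652 probes passed, 1444 higher and 1208 lower. ATF3 (3.22), ACTG2 (2.73), TAGLN (2.52), REEP5 (2.18) and H4C14 (2.05) were higher in the arrays labelled silencing, and HOXB8 (-2.43), CCND2 (-2.00), AP1S1 (-1.97), TNFRSF11B (-1.77) and LRRC17 (-1.75) were lower. The stress response list was higher with 7 of 7 named members called (camera adjusted p = 0.00315), as were the short-lived transcripts (0.0152) and the immediate early genes (0.0338), each with an adjusted p of 0.14 with an estimated correlation. With the position covariate 1280 probes passed, and the calls of TAGLN and TNFRSF11B ended. Without silencing replicate 2 there were 1627 probes, without silencing replicate 3 there were 1649, and without overexpression replicate 2 there were 1722.

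The 2 effects, each against its labelled control, differed at 1335 probes, 728 with a higher and 607 with a lower change in the arrays labelled silencing. Among these, ATF3 differed by 3.25, ACTG2 by 2.70 and HOXB8 by -2.89. Such a difference includes the gap between the 2 control groups. The stress response list differed with 7 of 7 named members called (camera adjusted p = 0.00243), the short-lived transcripts at 0.0105 and the immediate early genes at 0.0141, each with an adjusted p of 0.121 with an estimated correlation. The count was 846 without silencing replicate 3, 848 without silencing replicate 2, 859 without scrambled siRNA replicate 1 and 877 without scrambled siRNA replicate 2. By unmoderated contrasts, chosen after the data were seen, it was 273. The calls of TAGLN and SLC14A1 ended with a mean-variance trend and robust moderation (adjusted p = 0.114 and 0.129).

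Both labelled groups changed a part of the genes in the same direction. Of the probes called in both comparisons with the labelled controls, which share no array, 94 changed in the same direction, 65 higher and 29 lower, and 25 in opposite directions, where independent lists would give 10.1 and 10. Among the brighter probes alone, which hold most of the called probes, 94 changed in the same direction against 20.8 for independent lists and 24 in opposite directions against 20.7. Of the named genes 54 rose in both, including TOMM20 (1.85 in the arrays labelled silencing and 1.43 in those labelled overexpression), CIRBP (1.63 and 1.09), NTN1 (1.56 and 0.69), LZTFL1 (1.43 and 0.88) and CLDN1 (1.13 and 1.33). In both, 23 named genes fell, including CCN3 (-1.75 and -1.17), ERRFI1 (-1.03 and -1.27), AADAC (-0.96 and -0.66) and IFNAR1 (-0.73 and -0.57). Opposite changes were found for 21 named genes. CCND2, a cyclin that acts in G1, had the widest of these (-1.13 in the arrays labelled silencing and 1.06 in those labelled overexpression), and TPST1 (-0.92 and 0.53) and NCAPG2 (0.80 and -0.59) are further examples. With the control groups exchanged, 135 probes changed in the same direction and 8 in opposite directions. Of the named genes, 43 of those that rose in both, 11 of those that fell in both and 3 of the opposite ones were called against either control group. NTN1, AADAC, IFNAR1, TPST1 and NCAPG2 were chosen as examples after their values were seen.

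Across all 48803 probes the log2 changes of the 2 labelled groups had a Pearson r of 0.148 and a Spearman rho of 0.056, described across probes, which are not independent replicates. With the control groups exchanged r was 0.271, against 0 in 100 simulations without any effect. The simulations drew each probe independently, so they leave out deviations that arrays share across probes, such as the array axis described under the other observations. Such deviations can move r and the covariances without an effect, so these simulated values are no test of the relation. Pairs that share a control group correlate without any effect: against scrambled siRNA r was 0.457 where simulation gave 0.5, and against control 0.372 where it gave 0.499. The covariances were above their simulated values in each case, by 0.00978 and 0.00527 for the pairs that share a control group and by 0.00578 and 0.00986 for those that do not.

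**Figure D4:**
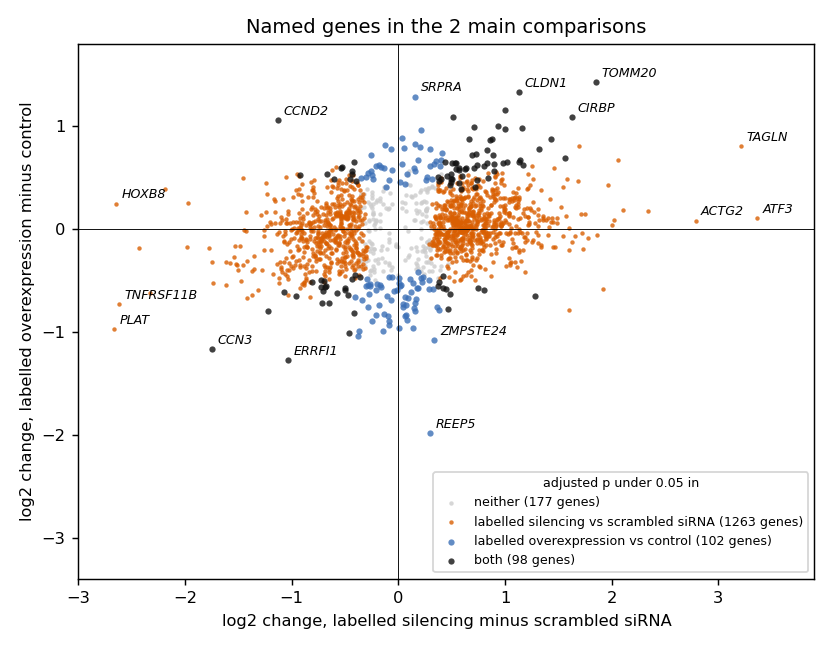
Log2 change of each of the 1640 named genes (points), in the arrays labelled silencing against scrambled siRNA (x axis) and in the arrays labelled overexpression against control (y axis), coloured by which test passed. ATF3 (3.36 on the x axis) and REEP5 (-1.99 on the y axis) lie along 1 axis, and TOMM20 and CCN3 lie off both.

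The deposited result table of the authors holds 1842 probes with an overall FDR of at most 0.049936. By the authors' p-values, 1721 of them differed between the arrays labelled silencing and scrambled siRNA at an unadjusted p under 0.05, 988 higher and 733 lower, and 265 had a fold change of at least 2. Between the arrays labelled overexpression and control there were 831, 453 higher and 378 lower, 16 of them at least 2-fold, and between scrambled siRNA and control 357. The deposited fold change of ATF3 for silencing against scrambled siRNA was 9.97, that of PTHLH -2.002 and that of SOX9 -2.06, where a negative value means lower by that factor. For overexpression against control the deposited fold changes were -1.53 for PTHLH (the authors' unadjusted p = 0.0185, from their 3 arrays per group in an analysis of variance) and -1.11 for SOX9. The column names of the authors' table follow the transfection labels, and its group means are those of the arrays so labelled, so the conflict with the sample titles applies to these values too.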

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

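The array axis, the unmoderated contrasts and the tests for probes that are easier to call and for a linear trend with position were chosen after the result was seen.

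The effect of 1 labelled group against its control differed from that of the other at 1335 probes, by a test of the difference itself in limma. In 100 regroupings of the 12 arrays, the real one and others drawn at random, 1 gave as many probes, the real one. The highest of the others gave 902, so a random grouping of these arrays is unlikely to give this count. Regrouping also mixes the arrays labelled silencing, which differ from every other group, with the rest. It therefore asks whether the groups have any structure and cannot decide whether the 2 effects differ. With 100 regroupings the smallest possible share is 1 in 100, and the labels do not say that replicates were separate cultures. The difference was 3.25 on the log2 scale for ATF3 (adjusted p = 3.21e-07), 2.70 for ACTG2 (5.4e-07), 2.50 for NBPF9 (0.00102), 2.40 for TAGLN (0.0108) and 2.39 for NBPF10 (0.000534), higher in the arrays labelled silencing. It was -2.89 for HOXB8 (adjusted p = 1.15e-06), -2.575 for CST1 (6.9e-05), -2.26 for SLC14A1 (0.0142), -2.23 for AP1S1 (0.000286), -2.19 for CCND2 (0.000931) and -0.90 for SOX9 (0.00595). These differences include the gap between the 2 control groups. For SOX9 scrambled siRNA minus control was 0.44, and the labelled groups differed directly by -0.46. Mean log2 intensity in scrambled siRNA and control was 9.65 and 8.65 for CST1, and 8.79 and 8.83 for ATF3. By unmoderated contrasts 273 probes passed, and the calls of NBPF9 (adjusted p = 0.0662), NBPF10 (0.0509), TAGLN (0.172), SLC14A1 (0.197), CCND2 (0.0615) and SOX9 (0.0703) ended. Probes of NBPF9 and NBPF10 can pick up other copies of the family, so these 2 values may not belong to the genes named.

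Between the arrays of 2 groups there are 10 splits of 6 arrays, too few for a share under 0.05. For labelled silencing against scrambled siRNA 1 split gave as many probes, the real one with 3430, and the highest other gave 0. For labelled silencing against control the values were 1 split, 2756 and 0, for labelled overexpression against scrambled siRNA 1 split, 298 and 0, and between the labelled groups 1 split, 2652 and 0. For labelled overexpression against control 2 splits gave at least the real 286, since 613 probes separated overexpression replicates 1 and 2 and control replicate 1 from the rest. Between scrambled siRNA and control all 10 splits gave at least the real 0, and 1107 probes separated scrambled siRNA replicates 1 and 2 and control replicate 1 from the rest. Both of these splits follow the array axis described under the other observations, a structure of the samples that the groups do not explain.

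In the arrays of both labelled groups the same probes were called in the same direction more often than independent lists would give (94 against 10.1, or 94 against 20.8 among the brighter probes), although opposite manipulations of 1 transcript are named in the labels. A linear trend with position along the BeadChip would change scrambled siRNA against control 1.25 times as much as labelled overexpression against control, but over the 94 probes the median of this ratio was -0.008, with quartiles of -0.152 and 0.132; an uneven effect of position stays open. Log2 changes had little linear relation to a probe's weight on the array axis. The r was -0.035 for labelled silencing against scrambled siRNA and -0.066 for labelled overexpression against control. Taking out the part that goes with this weight could therefore remove little, and 100% of the 94 probes kept most of both changes. These probes had passed the test in both comparisons, which favours a small spread within groups, so their share does not exclude the axis. Probes that are easier to call would give as many opposite as shared directions; shared directions were 3.76 times as frequent, and among the brighter probes opposite ones numbered 24 against 20.7 for independent lists (25 against 10 over all probes). A response to transfected DA125942 material of either kind, or a difference in delivery between the labelled groups and both controls, may lie behind it; the design does not separate these, and neither was tested.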

How the results depend on the processing

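The array axis as covariate and the unmoderated contrasts were chosen after the data were seen; the cause was not tested for any value below unless one is given. Of 1670 values of named genes under the alternatives, over 95 pairs of gene and comparison, 1597 kept direction and call, 71 kept the direction without the call and 2 reversed: with the position covariate, labelled silencing against control gave 0.0071 for ITGA2 and 0.0569 for PTHLH. In that comparison the groups lie at the ends of the BeadChip, so the covariate and the group difference overlap by design. Repeated quantile normalization, median centring and the axis covariate kept every call, and could hardly have done otherwise. The total of 1597 includes them and is no measure of stability. With position the probe counts were 2501 for labelled silencing against scrambled siRNA, 157 for labelled overexpression against control, 474 for labelled silencing against control and 1280 between the labelled groups. Of the original 3430, 286, 2756 and 2652 probes, 1679, 61, 237 and 780 were among these. With position the probe counts rose from 298 to 419 for labelled overexpression against scrambled siRNA and from 1335 to 1932 for the difference of the effects. In that difference position cancels, since the groups of both main comparisons differ by -4 in mean position. There the covariate leaves every log2 change as it was and alters only the residual spread. Labelled overexpression and scrambled siRNA lie only 1 apart in mean position, so neither rise tests an effect of position. With the axis covariate the probe counts were 5386 for labelled silencing against scrambled siRNA, 1125 for labelled overexpression against control, 4641 for labelled silencing against control, 1167 for labelled overexpression against scrambled siRNA, 16 for scrambled siRNA against control, 4534 between the labelled groups and 3084 for the difference of the effects. The axis scores sum to 0 in each group and come from the residuals of the same arrays, so by construction this covariate leaves every log2 change as it was and lowers the residual spread, and its counts are too high to be read as calls. In the same order the unmoderated contrasts gave 1651, 42, 1193, 44, 1, 1105 and 273, and ended the calls of 11 of the 24 named genes for labelled overexpression against control and of SLC14A1 for labelled silencing against control (adjusted p = 0.0775). With a minimum of 1.5-fold, which only removes probes, the counts were 1694, 178, 1352 and, between the labelled groups, 1272. With only the arrays compared, labelled overexpression against control gave 39, while labelled silencing against scrambled siRNA gave 4912 and the comparison of the labelled groups 3479. Leaving out 1 replicate at a time gave 2262 to 2973 probes for labelled silencing against scrambled siRNA, 83 to 469 for labelled overexpression against control, 1680 to 3239 for labelled silencing against control, 118 to 255 for labelled overexpression against scrambled siRNA, 0 to 3 for scrambled siRNA against control, 1627 to 2477 between the labelled groups and 846 to 1949 for the difference. Lists called were 0 with an estimated correlation in both main comparisons, and with fry, which does not compare a list with other genes, 11 for labelled silencing and 4 for labelled overexpression. Leaving out replicates gave 0 to 1 lists for labelled overexpression against control. The correlation across probes was 0.271 with the controls exchanged, 0.457 against scrambled siRNA and 0.372 against control for both, where shared arrays raise it, and 0.097 to 0.171 without single replicates. With position as a covariate it was 0.542, and -0.029 with the controls exchanged. Both changes then hold the same fitted slope, which alone can move this correlation. Arrays with the same replicate number were not treated as pairs in the main fit. The mean correlation of their deviations was 0.089 over 18 pairs, from -0.287 to 0.452, with 6 above 0.1 and a mean of -0.047 for other pairs, and 5 arrays were closest to one of their own number. The 6 pairs were replicates 1 and 3 of scrambled siRNA, labelled overexpression and control, from 0.254. Pairs of unlike number reached 0.455, so a shared replicate number stays open. Within every group the number rises with position, so a block for it also takes up part of any trend with position. With the replicate number as a block the counts were 3963, 404, 3236, 438, 0, 3180 and 1698, and PTHLH passed for labelled overexpression against scrambled siRNA (-0.75, adjusted p = 0.0321). With position as a covariate, the probes called in both labelled groups were 79 in the same direction and 0 in opposite directions, and 16 and 3 with the controls exchanged. The groups of both main comparisons differ by -4 in mean position, so 1 fitted slope moves both changes alike and the first of these pairs of counts tests nothing. Under median centring and repeated quantile normalization the median log2 change of all probes lay within 0.0048 of 0 in every comparison. What the deposited normalization removed cannot be recovered, and signal over background limits what dim probes can show.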

Other observations

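The families by symbol, the array axis, its tests against position, replicate number and noise, and the choice of zinc finger genes came after the data were seen.

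Ribosomal protein genes, grouped by symbol, were lower in the arrays labelled silencing than in scrambled siRNA. All 9 named members fell, against 572 of the 1631 other named genes (Fisher's exact test, p = 8.44e-05, adjusted p = 0.00101 over 12 tests of 6 families), with a median log2 change of -0.675. RPS9 (-1.24), RPL32 (-1.035) and RPL34 (-0.96) had the largest changes. In the arrays labelled overexpression 1 of the 9, RPL12, was higher than in control (0.49). Of the HOX genes 5 fell and 1 rose of 7, with HOXB8 (-2.65), HOXB5 (-1.05) and HOXB7 (-0.98) lower and HOXB2 (0.52) higher, and the share of falls did not pass the test (adjusted p = 0.223). Of 5 integrin genes 4 fell (adjusted p = 0.169), and of 4 collagen genes COL4A5 (-1.24), COL4A6 (-1.07) and COL15A1 fell and COL8A1 (1.05) rose (adjusted p = 0.223 for the falls). All 5 NBPF genes rose (adjusted p = 0.0968), and of 36 solute carrier genes 14 rose and 14 fell (adjusted p = 0.421 for rises and 0.725 for falls). The named genes had been selected on these samples, so these shares describe that selection. Fisher's test also treats the genes as independent, although genes of a family on the same arrays can vary together, so its p-values may be too small. The adjustment leaves out the zinc finger genes described below.

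Further examples of the 21 named genes with opposite changes in the 2 labelled groups were chosen after their values were seen. EIF4EBP2, a translation repressor, changed by -0.53 in the arrays labelled silencing and 0.60 in those labelled overexpression, and RPL12, a ribosomal protein gene, by -0.46 and 0.49. SPOCK1, a proteoglycan, changed by -0.60 and 0.48, and the zinc finger gene ZNF462 by 0.47 and -0.77.

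A single axis held 41.7% of the variance of the deviations from the group means over the brighter 24401 probes, where 100 shuffles of each probe's deviations within groups gave at most 19.7%. Independent noise of single probes cannot give such a share. The scores set control replicate 1 (0.637) and overexpression replicate 1 (0.266) at 1 end and control replicate 2 (-0.36), scrambled siRNA replicate 3 (-0.359) and overexpression replicate 3 (-0.343) at the other; the arrays labelled silencing lay between -0.028 and 0.027. Within groups the score had a Pearson r of -0.721 with position along the BeadChip (exact permutation p = 0.0278) and a Spearman rho of -0.731 (exact permutation p = 0.0293), and r was -0.719 without the 2 farthest samples. The p of r adjusted over the 2 relations tested was 0.0556, so a gradient along the BeadChip stays open. So does a shared replicate number, with an adjusted exact permutation p of 0.12, and no biological explanation was tested. Within every group the replicate number rises with position, so the design cannot tell these 2 explanations apart.

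Zinc finger genes named ZNF and a number were mostly higher in the arrays labelled silencing than in scrambled siRNA: 47 of 61 rose and 6 fell, against 733 and 575 of 1579 other named genes, a family singled out for these values, with ZNF664 at 1.47 and ZNF442 at 1.43 and ZNF792 at -1.19. Against control 45 rose and 5 fell, and in the arrays labelled overexpression 1 rose and 1 fell against control. Named genes matched on mean intensity reached a share of rises of at most 70.5% against 77% here (permutation p = 1e-04, the smallest that 10000 resamples can give). The family was chosen for this share, and the p does not allow for that choice or for genes that vary together, so it describes these genes only. The median log2 change was 0.547, and 0.557 without the part that goes with the array axis. Log2 changes had an r of only -0.035 with the axis weight, so little could be removed there. With 16 added before log2, 47 rises kept their call. These probes had a mean log2 intensity of 8.58, where adding 16 changes little, so this cannot decide on the scale of dim probes. Cross-hybridisation between paralogs and a short half-life of these transcripts were not tested, as probe sequences and decay rates were not at hand, so a rise of the family may be proposed only as a hypothesis.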
